A study of Saccharomyces cerevisiae and Homo sapiens with 32 samples.

How the data were processed

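Footprint counts of 30 yeast libraries and 2 HEK293T libraries were analysed. The yeast libraries formed 15 experiments in 13 conditions, each an input library of monosomes and the streptavidin pulldown made from it. Per the labels' protocols, yeast ribosomes carried the AviTag on Rpl16a and Rpl16b, human ribosomes carried it on mouse RPL10A, and BirA was free in the cytosol or fused. It sat at the C-terminal end of Sec63 and N-terminally in fusions with Ssh1, with Heh2 and Ssh1, with the tail anchor of Ubc6 and, in human cells, with Sec61β. The Ssh1 fusions replaced the SSH1 locus, while the Ubc6 fusion stood beside an intact UBC6. Per the labels' protocols, yeast grew with 0.125 ng/ml biotin, cycloheximide was given at 100 µg/ml for 2 min before biotin where it was used, and biotin was added to 10 nM in yeast and 50 µM in human cells. RNase I made the yeast footprints and micrococcal nuclease the human ones.

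The deposited tables gave raw counts of footprint reads per gene for each library, per the file headers, with no normalization. The deposited tables also gave RPKM values, which the authors scaled by coding length and by reads per library. The deposited tables further held log2 ratios of pulldown over input RPKM that the authors formed within each experiment. The submitters' processing notes name CASAVA and the sacCer3 and hg19 genomes. The aligner and the rules for reads that fit several genes are not given in the sources used here. Values were computed from the counts, except the input levels of SSH1, HEH2 and SEC65, which are deposited RPKM values. The RPKM columns were used for these strain checks and to check the library totals, which were 1.00 to 1.20 times the sum over the listed genes. No reported enrichment was taken from the deposited log2 ratios. In the human table a log2 ratio is given for 4804 genes, and the smallest input among them is 100 footprints. The yeast table held 5 further per-sample columns that belong to no sample here, and they were not used here.

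Yeast tables held 6692 genes, of which 6008 matched a RefSeq locus tag of the R64 assembly, the source of coordinates. Genes outside that list, overlapping frames and near-identical copies (such as hexose transporters, COS genes and Ty elements) can share footprints, and their values are uncertain. The human table held 21126 genes without symbols. Lists of 26 yeast gene groups were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, save those said below to be later. Of the lists, 25 were used for enrichment. Among them were 14 secretory lists (195 genes together) and 6 cytosolic and nuclear ones (244 reference genes, 138 of them ribosomal proteins). The remaining list, of heat shock and unfolded protein response genes, was used for input libraries. The classes secretome, SRP-dependent, cycloheximide-dependent and sec66Δ-dependent are the authors' columns.

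For the conditions with 2 experiments, edgeR 4.0.16 in R 4.3.3 fitted all 30 yeast libraries together (filterByExpr, TMM scaling, quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with a term per experiment. Each pulldown was so compared with its own input. The pairing of input and pulldown comes from the sample titles. As a check, deviations from the condition means went together within experiments, with a correlation across genes of 0.81 for Sec63 (4983 genes) and 0.80 for Heh2-Ssh1 (4377 genes). Genes are not independent replicates. All conditions shared 1 estimate of the spread (residual degrees of freedom come from the 2 replicated conditions, common biological coefficient of variation 0.115, prior degrees of freedom 4.82). Replicates were numbered in the order of deposit. Nothing in the labels says that replicate experiments came from separate cultures, so the p-values measure the spread between these samples. Standard errors are the log2 fold change divided by the square root of the F value. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, prior count 2) and again with an estimated correlation, with Benjamini-Hochberg adjustment over 25 lists in each comparison. The version with an estimated correlation rested on 2 residual degrees of freedom. Its lack of calls can therefore not show what correlation between genes does to the lists. The median and the camera direction differed in sign only for ribosomal proteins in the difference of the fusions (median -0.03, camera upwards, adjusted p 0.711).

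Conditions with 1 experiment got no test. The log2 ratio of pulldown to input share, with 0.5 added to each count, was computed for genes with at least 100 input footprints and centred on the median of the 244 reference genes. Intervals of 95% cover counting error only, and reads without molecular identifiers are not independent molecules. A list's percentile is its rank among 10000 random lists of the same size drawn from 20 bins of input level, and it describes these libraries. Human reference lists could not be matched without symbols, so human values were centred on genes in none of the secretome, mitochondrial and peroxisomal classes (centre -0.72). Between replicate experiments a gene's value had a standard deviation of 0.235 and the median of the secretory lists 0.345, which give 0.332 and 0.488 for a difference of experiments. Replicates correlated across genes at r 0.979 for Sec63 and 0.966 for Heh2-Ssh1 (4981 genes). Yeast libraries held 6850721 to 56463694 footprints.

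Genes were named by a rule. For each tested enrichment these were the 12 highest and 6 lowest past the threshold, with the same sign in both experiments and at least 100 input footprints in each. For the difference they were the 8 largest each way past the threshold, and for single experiments the 8 highest and 8 lowest with at least 100 input footprints. The highest and lowest members of discussed lists, the genes changed in the strains and 12 fixed marker genes could be named in any comparison. HEH2, named for the difference, was a lowest list member.

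The alternatives were DESeq2 1.42.0, total footprints without TMM, scaling on the reference genes, no filter, at least 100 input footprints in every input, no term per experiment, the libraries of the compared fusions alone, each replicate left out, and a log2 fold change of at least 1. For single experiments they were centring on total footprints or on all genes, input minimums of 30 and 300, and a pseudocount of 5. Where a replicate was left out, the lone experiment was assumed to vary like the other condition. The standard deviation across genes of replicate 2 minus replicate 1 was 0.202 for Sec63 and 0.413 for Heh2-Ssh1. Counts from these fits therefore reflect the spread of the other fusion as well. Alternatives with normalized values were not needed, because counts were used. The fit without the 37 °C libraries and centring without ribosomal proteins were chosen after seeing the data. Against an alternative, a tested gene was taken as kept when its direction and side of the threshold held, a count when it lay within 1.5 times, and an untested value when it moved by less than the replicate standard deviation. A change of sign counted as a reversal when either value had passed the threshold, or for list medians when the main value was larger than its spread. For HEK293T the bootstrap interval over genes stood in for the replicate spread.

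Both procedures were tested on simulated data with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. With 200 genes changed in the Sec63 comparison, the edgeR fit on 5707 genes recovered 14 of 50 genes changed by 0.5, 49 of 50 changed by 1, 48 of 50 changed by 2 and 49 of 49 changed by 3. It called 3 of 5508 unchanged genes. That simulation used 1 mean input profile, 1 common dispersion and independent genes changed both ways. It therefore does not show the error rate or the scaling where secretory genes shift together. In a simulated single experiment on 4877 genes with the secretory lists shifted by 2, list medians came out at 1.96 to 2.02 and other lists at -0.01 to 0.02. Of the intervals 95.3% covered the true value. Figures were drawn with matplotlib 3.10.9.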

Results

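Ribosome profiling sequences the mRNA fragments that ribosomes shield from nuclease, so the footprints on a gene show how much of its protein was being made. In the proximity-specific form used here, the biotin ligase BirA sat at a chosen place in the cell and the ribosomes carried an AviTag, the peptide that BirA biotinylates, so a streptavidin pulldown kept the ribosomes that had been near the ligase. The data held 30 budding yeast libraries from 15 experiments and 2 libraries from HEK293T, a human embryonic kidney cell line. Each experiment was an input library of all ribosomes and the pulldown made from it. The yeast ligase was either free in the cytosol or anchored at the endoplasmic reticulum (ER) through Sec63 (a partner of the protein-conducting channel), through Ssh1 (the pore of another such channel), through Ssh1 with Heh2, or through the tail anchor of Ubc6. Cycloheximide, which freezes ribosomes on the mRNA, was present in 11 of the 15 yeast experiments. Of 13 yeast conditions, the Sec63 fusion and the Heh2-Ssh1 fusion, both with cycloheximide and 7 min of biotin, had 2 experiments each, and every other condition had 1. Yeast inputs held 10788357 to 56463694 footprints and yeast pulldowns 6850721 to 45143048. The human input held 3156031 footprints and its pulldown 2144158.

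Footprints on secretome genes, the authors' class of 1145 genes for proteins that enter the secretory pathway, made up 14.4% to 20.2% of every yeast input. With cytosolic BirA the pulldown stayed at 14.8% beside an input of 15.9%. The highest shares were in the Heh2-Ssh1 pulldowns, at 70.7% and 69.5%, followed by the Ubc6 pulldowns at 64.0% after 7 min and 59.9% after 2 min. The sec65-1 pulldowns with Sec63-anchored BirA, labelled for 2 min with cycloheximide, held 58.9% at 25 °C and 55.4% at 37 °C. The Sec63 pulldowns after 7 min with cycloheximide held 49.4% and 50.6%, the sec66Δ pulldown with Ubc6-anchored BirA held 49.8%, and the Ssh1 pulldown after 2 min held 34.2%. Wilson 95% intervals lay within 0.0355 percentage points of each yeast share and cover counting error only.

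The first tested comparison asked which genes were being translated near Sec63 after 7 min of biotin with cycloheximide (2 experiments, log2 pulldown over input, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 5864 genes). The pulldown was enriched for 1306 genes and depleted for 1307, and 3251 did not pass. Of the 1082 secretome genes tested, 916 were enriched, 6 were depleted and 160 did not pass, with a median of 1.99. Of the 4782 other genes, 390 were enriched and 1301 were depleted. The depleted count was 453 without replicate 1 of Sec63 and 232 without replicate 2, and 679 with DESeq2, while the enriched count stayed between 1043 and 1716 in the alternatives tried. Enriched genes made up 50.0% of the calls and 24.3% with total footprints, which moved the median of all genes to -0.53. Scaled on the cytosolic and nuclear reference genes, 1459 genes were enriched and 839 depleted.

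Among genes with at least 100 input footprints in both inputs, HPF1, a cell wall mannoprotein, was enriched by 2.95 ± 0.19 (SE, n = 2, edgeR adjusted p 6.5e-05), and MSB2, a mucin-like osmosensor of the plasma membrane (chromosome VII, 516943 to 520863, R64 assembly), by 2.94 ± 0.19 (edgeR adjusted p 6.5e-05). PDI1, the disulfide isomerase of the ER lumen (chromosome III, 48653 to 50221), was enriched by 2.90 ± 0.21 (edgeR adjusted p 7.3e-05). PRY3, AGA1, UTH1, CPR2, CPR4, SCW4, SIM1 and ERV25 followed at 2.82 to 2.76. Footprints assigned to YOR248W, at 2.89, are uncertain because it is not in the RefSeq gene list and can share reads with an overlapping gene. At the other end, FUN12, the translation initiation factor eIF5B, was depleted by -1.66 ± 0.15 (edgeR adjusted p 1.5e-04), FAS2, a fatty acid synthase subunit, by -1.53 (edgeR adjusted p 4.4e-04, but 0.0573 without replicate 2 of Sec63), and RPO31, the largest subunit of RNA polymerase III, by -1.52. YJL047C-A, a short open reading frame, lay lowest at -4.42 ± 0.80, and YGL088W, which overlaps a small nucleolar RNA, lay at -2.93 ± 0.83. Outside the secretome, pulldown over input fell with protein length in both Sec63 experiments (rank correlation across genes -0.48 and -0.53). No value was adjusted for length, so depletion of single genes was not separated from this trend.

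Every secretory gene list fixed before the data were examined had a positive median near Sec63. Limma's camera, with its preset correlation between genes, called 20 of the 25 lists, with an adjusted p of 2.5e-10 for the ER chaperones. With a correlation estimated from these libraries it called none (adjusted p of the lists 0.377 or more, no list at an unadjusted p under 0.05). The estimated correlation was 0.753 for the ER chaperones. Over the secretory lists it ran from 0.207 (translocon and SRP receptor) to 0.988 (O-mannosyltransferases), far above the preset 0.01. The calls with the preset correlation thus assume much less correlation in these lists than was estimated. Lists with an estimated correlation under the preset 0.01 lost their call too, such as peroxisomal membrane proteins (-0.0114, camera adjusted p 1.97e-04 and 0.377). With 2 residual degrees of freedom that version cannot settle whether correlation removes the calls. All 16 ER chaperones and folding enzymes passed (median 2.51, with KAR2, the ER Hsp70, at 2.50), and the count was 16 as well when adjusted over the list alone. All 31 plasma membrane transporters, all 18 Golgi mannosyltransferases, all 12 ER-Golgi cargo receptors, all 9 oligosaccharyltransferase subunits, all 8 nuclear envelope membrane proteins, all 6 protein O-mannosyltransferases and all 5 subunits of the V-ATPase membrane sector passed, with medians of 1.97, 2.21, 2.40, 2.27, 1.83, 2.15 and 2.39. Among the transporters HXT6, at 4.52, is uncertain, because it had 0 input footprints in both Sec63 experiments and is a near-identical copy of HXT7. Among GPI-anchored surface proteins 18 of 20 passed (19 when adjusted over the list alone, median 2.44), and CCW12 did not, at 0.32. Of the secreted and cell wall proteins 16 of 17 passed (median 2.26). SUC2, secreted invertase, was among the lowest of them at 0.62 ± 0.17 (edgeR adjusted p 0.0238, but 0.0713 and 0.141 without replicate 1 and replicate 2 of Sec63). Vacuolar hydrolases passed in 8 of 9 cases (9 when adjusted over the list alone, median 2.22), PRB1 missing at 0.50. The other lists were 19 of 20 sterol and lipid enzymes (median 2.21, ERG1 not past at -0.32 but depleted when adjusted over the list alone), 14 of 16 N-glycan assembly genes (median 2.04, DPM1 not past at -0.12) and 7 of 8 translocon and SRP receptor genes (median 2.14, SEC72 not past at -0.04). Without replicate 1 or replicate 2 of Heh2-Ssh1, CCW12 and PRB1 passed as enriched and ERG1 passed as depleted.

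Lists of other compartments had lower medians near Sec63 than the secretory lists, though no test compared the 2 kinds of list. Their values were not adjusted for protein length, with which pulldown over input fell outside the secretome. Tail-anchored proteins, which enter the membrane after translation, had a median of -0.09 (0.03 when scaled on the reference genes), and 3 of 23 were enriched (1 when adjusted over the list alone). TLG2, an endosomal t-SNARE, was the highest of them at 0.93 ± 0.10 (edgeR adjusted p 3.0e-04). Peroxisomal membrane proteins were enriched in 9 of 10 cases (median 0.95), led by ANT1, the peroxisomal adenine nucleotide carrier, at 1.98. Of 30 respiratory chain and TCA cycle genes 18 were depleted (median -0.56, KGD1 lowest at -1.20) and 2 enriched, SDH3 highest at 1.92. Among the 21 cytosolic chaperones 18 were depleted (19 when adjusted over the list alone, median -0.52, SSE1 lowest at -0.81), and 10 of 31 proteasome genes (9 when adjusted over the list alone, median -0.27), 7 of 18 elongation and initiation factors (median -0.31) and 4 of 18 glycolytic enzymes (median -0.41) were depleted too. The 138 ribosomal protein genes had a median of -0.07 with 2 enriched and 4 depleted (0 in all when adjusted over the list alone), a sign that turned to 0.04 when scaled on the reference genes. Mitochondrial carriers (2 of 19 depleted, 1 when adjusted over the list alone, median -0.15), mitochondrial outer membrane proteins (3 of 13 enriched and 1 depleted, median 0.16, but -0.32 with total footprints; OM14 highest at 1.16) and histones and RNA polymerase II (2 of 18 depleted, median -0.01, or 0.11 when scaled on the reference genes, RPO21 lowest at -1.39) were near the middle. These counts moved with the experiments in the fit. Without a replicate of 1 fusion, the spread came from the other fusion alone. Replicates of Heh2-Ssh1 differed more than those of Sec63 (standard deviation across genes 0.413 against 0.202). The counts below so reflect that spread as well as the lists. The inputs of replicate 1 and replicate 2 also differed. Ribosomal protein genes took 16.5% and 8.92% of input footprints in Heh2-Ssh1, and 17.1% and 13.5% in Sec63. Without replicate 1 or without replicate 2 of Sec63, 0 cytosolic chaperones, 0 proteasome genes, 0 glycolytic enzymes and 0 carriers were depleted (SSE1 at an edgeR adjusted p of 0.227 and 0.329), while the median of the cytosolic chaperones was -0.57 and -0.51. There were 4 and 3 depleted respiratory genes, 2 and 2 translation factors, 3 and 0 ribosomal proteins and 1 and 0 outer membrane genes. Enriched were 1 and 1 tail-anchored genes and 1 and 0 ribosomal proteins. Without replicate 1 or replicate 2 of Heh2-Ssh1, 12 and 11 glycolytic enzymes, 18 and 16 ribosomal proteins, 16 and 16 proteasome genes, 3 and 3 carriers, 3 and 2 outer membrane genes and 2 and 2 tail-anchored genes were depleted. Enriched were 13 and 14 ribosomal proteins, 5 and 7 outer membrane, 4 and 5 tail-anchored and 3 and 4 respiratory genes, 2 and 2 histone and polymerase genes, 1 and 1 carriers and 0 and 1 proteasome genes.

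The Heh2-Ssh1 fusion was compared with its input in the same way (2 experiments). Its pulldown was enriched for 1052 genes and depleted for 764. Of the secretome genes 902 were enriched, 13 were depleted and 167 did not pass, with a median of 3.0. Of the other genes 150 were enriched and 751 were depleted. SSH1, whose own product carried the ligase (chromosome II, 768943 to 770415), was the most enriched gene with at least 100 input footprints in both inputs, at 5.19 ± 0.17 (SE, n = 2, edgeR adjusted p 7.5e-06), with 731 and 1169 input footprints against 8960 and 25801 in the Sec63 inputs. MSB2 (4.52), PDI1 (4.44 ± 0.23, edgeR adjusted p 8.0e-06), CPR2 (4.29), SCW4 (4.26), SHE10 (4.25), HPF1 (4.25) and ECM33 (4.24) came next. YOR248W, YMR304C-A, YBR206W and YBL083C, at 4.83 to 4.32, are not in the RefSeq list and can share reads with overlapping genes. The lowest with at least 100 input footprints in both inputs were the Ty element frames YPR158C-C and YPR158C-D, which have near-identical copies, HBT1 (-1.14 ± 0.14, edgeR adjusted p 7.2e-04), MLP1 (-1.06), a nuclear basket protein, DEF1 (-0.96) and OSW2 (-0.94). OSW2 passed in 9 of 12 alternatives, each Ty frame in 11 of 12, HBT1 and DEF1 in 12 of 13 and MLP1 in 13 of 13. Outside the secretome, pulldown over input fell with protein length here too (rank correlation across genes -0.21 and -0.37), and no value was adjusted for it. The depleted count was 404 and 232 without replicate 1 and replicate 2 of Sec63, 1447 without replicate 2 of Heh2-Ssh1 and 231 with DESeq2, while the enriched count stayed between 828 and 1148 in the alternatives tried. Enriched genes made up 57.9% of the calls, 73.1% when scaled on the reference genes, and 15.9% with total footprints, which moved the median of all genes to -1.45.

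By list, all 16 ER chaperones (median 3.85), all 31 plasma membrane transporters (3.42), all 18 Golgi mannosyltransferases (3.64), all 12 cargo receptors (3.36), all 9 vacuolar hydrolases (3.82), all 8 nuclear envelope proteins (2.67), all 6 O-mannosyltransferases (3.84) and all 5 V-ATPase membrane subunits (3.05) were enriched near Heh2-Ssh1. The nuclear envelope list holds HEH2 and the translocon list holds SSH1, the genes of this fusion. GPI-anchored proteins passed in 18 of 20 cases (3.65), sterol and lipid enzymes in 18 of 20 (3.47), secreted and cell wall proteins in 16 of 17 (3.62), N-glycan assembly genes in 14 of 16 (3.36), and 7 each of the 9 oligosaccharyltransferase subunits (8 when adjusted over the list alone, 3.68) and the 8 translocon genes (3.09) did, with OST5 (-0.16) and SEC72 (-0.08) among those not past. Tail-anchored proteins had no enriched member and 5 of 23 depleted (4 when adjusted over the list alone, median -0.25, camera adjusted p 0.0348, and 0.32 with an estimated correlation), SED5, a Golgi t-SNARE, lowest at -0.69. Peroxisomal membrane proteins were enriched in 8 of 10 cases, with a median of 0.67 that turned to -0.68 with total footprints, where it still lay above the all-gene median. The depleted members were 5 of 30 respiratory genes (3 when adjusted over the list alone, median -0.19, SDH3 enriched at 1.38), 2 of 21 cytosolic chaperones (0 when adjusted over the list alone, median -0.19). Further depleted were 6 of 31 proteasome genes (4 when adjusted over the list alone, -0.23), 3 of 18 histone and polymerase genes (0 when adjusted over the list alone, -0.14), 2 of 18 elongation and initiation factors (-0.13, with 1 enriched) and no glycolytic enzyme (-0.16). Of 138 ribosomal proteins 3 were enriched and 1 depleted (0 in all when adjusted over the list alone, median -0.04, and 0.04 when scaled on the reference genes). No mitochondrial carrier passed (median 0.01, but -1.33 with total footprints, where all genes had a median of -1.45) and 1 of 13 mitochondrial outer membrane genes was enriched (0 when adjusted over the list alone, -0.09). The small counts moved with single experiments. Without replicate 1 or replicate 2 of Sec63 the depleted were 0 and 0 chaperones, 0 and 0 proteasome genes, 0 and 0 histone and polymerase genes, 0 and 0 ribosomal proteins, 1 and 0 respiratory genes, 1 and 1 tail-anchored genes and 1 and 1 translation factors, and the enriched 1 and 0 translation factors and 1 and 0 outer membrane genes. Without replicate 1 or replicate 2 of Heh2-Ssh1 the depleted were 6 and 9 chaperones, 14 and 12 proteasome genes, 3 and 8 histone and polymerase genes, 3 and 25 ribosomal proteins, 12 and 9 respiratory genes, 6 and 10 tail-anchored genes, 6 and 7 translation factors, 12 and 0 glycolytic enzymes, 1 and 0 carriers and 1 and 1 outer membrane genes. The enriched were 5 and 7 ribosomal proteins, 1 and 2 respiratory genes, 3 and 0 translation factors, 0 and 3 carriers, 0 and 2 outer membrane genes and 0 and 1 tail-anchored genes, and 1 N-glycan gene without replicate 1 and 1 sterol and lipid gene without replicate 2 were depleted. OST5 passed as depleted without replicate 2 of Heh2-Ssh1 (-0.51, edgeR adjusted p 0.011), and 5 peroxisomal genes were enriched there. Camera called 19 of the 25 lists with the preset correlation and none with an estimated one (adjusted p 0.32 or more, no list at an unadjusted p under 0.05). The second version again rested on 2 residual degrees of freedom.

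**Figure D1:**
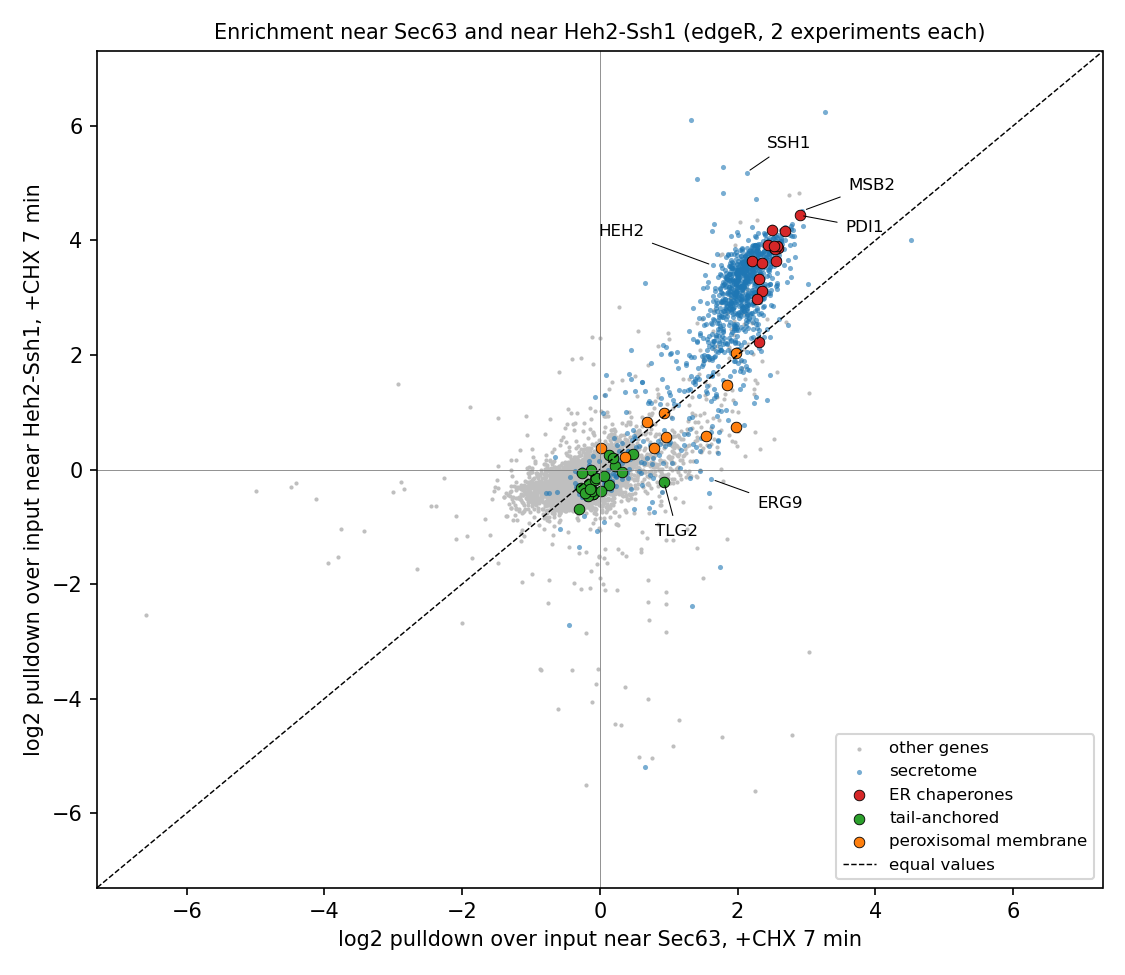
Log2 pulldown over input of each tested gene near Sec63 (horizontal) and near Heh2-Ssh1 (vertical), mean of 2 experiments each, with secretome genes, other genes and the members of 3 lists in separate colours and the line of equal values. The secretome medians are 1.99 near Sec63 and 3.0 near Heh2-Ssh1, and SSH1 stands highest of the labelled genes.

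Both fusions enriched 1015 genes in common, where independent lists of these sizes would share 234.3, depleted 478 in common, and took 8 in opposite directions. Both ligases sat at the ER, so an overlap above the independent number was built into the design. The direct test of the difference (Sec63 minus Heh2-Ssh1, edgeR quasi-likelihood) found 169 genes higher with Sec63 and 667 higher with Heh2-Ssh1. Of the 667, 502 were secretome genes and 530 were enriched with both fusions, and the secretome had a median of -0.97. Between replicates (2 minus 1) the secretome had a median difference of -0.56 for Heh2-Ssh1 and -0.17 for Sec63. A shift common to secretory genes was not separated from differences of single genes, so the calls are not that many separate differences. Without replicate 2 of Sec63 the test found 0 genes higher with Sec63 (195 at an unadjusted p under 0.05) and 1 higher with Heh2-Ssh1 (607 unadjusted), and without replicate 2 of Heh2-Ssh1 it found 774 and 1082. Without replicate 1 of Sec63 the counts were 84 and 523, and without replicate 1 of Heh2-Ssh1 they were 339 and 739. DESeq2 found 103 and 586. Scaling on total footprints moved the all-gene median to 0.81 and gave 3816 and 260, so that 93.6% of calls rather than 20.2% were higher with Sec63. In the fit without the sec65-1 37 °C libraries, chosen after seeing the data, the counts were 227 and 281 (44.7%). The secretory lists with the largest differences were O-mannosyltransferases (6 of 6 lower with Sec63, median -1.67), Golgi mannosyltransferases (17 of 18, -1.54), vacuolar hydrolases (8 of 9, -1.52) and plasma membrane transporters (21 of 31, or 27 when adjusted over the list alone, -1.44). Without replicate 2 of Sec63 only 1 gene of all 25 lists, a plasma membrane transporter, was called, and without replicate 1 of Sec63 the vacuolar count was 5.

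Other secretory lists were also lower with Sec63 in the direct test. These were N-glycan assembly (12 of 16, or 13 when adjusted over the list alone, -1.38), secreted and cell wall proteins (9 of 17, or 14 when adjusted over the list alone, -1.36), ER chaperones (13 of 16, or 14 when adjusted over the list alone, -1.31, KAR2 at -1.68 ± 0.34 with an edgeR adjusted p of 0.0227), GPI-anchored proteins (15 of 20, or 17 when adjusted over the list alone, -1.28), sterol and lipid enzymes (13 of 20, or 16 when adjusted over the list alone, -1.24), the oligosaccharyltransferase (6 of 9, -1.19, camera adjusted p 0.0684, and 0.505 with an estimated correlation) and cargo receptors (5 of 12, or 11 when adjusted over the list alone, -1.0). The translocon and SRP receptor genes (4 of 8, or 5 when adjusted over the list alone, -0.78), V-ATPase membrane subunits (1 of 5, -0.74) and nuclear envelope proteins (3 of 8, or 4 when adjusted over the list alone, -0.68) had the smallest medians, which turned to 0.10, 0.14 and 0.20 with total footprints. The translocon calls include SSH1 (-3.06) and the nuclear envelope calls include HEH2 (-1.92). Both genes are part of the Heh2-Ssh1 fusion, and each was the lowest member of its list. Tail-anchored proteins lay on the other side (1 of 23 higher with Sec63, median 0.20, camera adjusted p 6.2e-04, but 0.505 with an estimated correlation), as did peroxisomal membrane proteins (2 of 10, 0.26) and mitochondrial outer membrane proteins (2 of 13, 0.12). No gene passed among mitochondrial carriers (-0.27), glycolytic enzymes (-0.23), ribosomal proteins (-0.03), cytosolic chaperones (-0.35) or the proteasome (-0.07). Among respiratory genes 3 of 30 were lower and 1 was higher (-0.23), with 2 of 18 elongation factors (3 when adjusted over the list alone, -0.25) and 2 of 18 histone and polymerase genes (0.13) lower. With total footprints these medians outside the secretory lists lay above 0, beside an all-gene median of 0.81. Without replicate 1 of Sec63 the counts lower with Sec63 were 6 ER chaperones, 4 GPI-anchored, 4 secreted and 3 oligosaccharyltransferase genes, 1 ribosomal protein and 0 respiratory, translation factor, and histone and polymerase genes, with 1 outer membrane gene higher. Without replicate 1 of Heh2-Ssh1 they were 8 cargo receptor and 4 translation factor genes, 3 ribosomal proteins and 1 cytosolic chaperone, with 2 respiratory genes, 1 translocon gene and 1 plasma membrane transporter higher. Without replicate 2 of Heh2-Ssh1 they were 15 secreted, 12 cargo receptor, 5 V-ATPase, 7 nuclear envelope, 7 respiratory, 6 glycolytic and 5 translation factor genes, 4 carriers, 4 cytosolic chaperones, 3 ribosomal proteins and 1 outer membrane gene. In that fit 9 tail-anchored genes, 8 ribosomal proteins, 6 histone and polymerase, 3 respiratory, 3 peroxisomal, 2 proteasome, 2 translation factor and 2 oligosaccharyltransferase genes and 1 translocon gene were higher. Camera called 16 of the 25 lists with the preset correlation and none with an estimated one (adjusted p 0.505 or more, no list at an unadjusted p under 0.05). The second version again rested on 2 residual degrees of freedom.

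Single genes stood out in the direct test. ERG9, squalene synthase, which is held in the ER membrane by its C-terminal end, was enriched near Sec63 but not near Heh2-Ssh1 (difference 1.78 ± 0.18, edgeR adjusted p 0.0145, and 3.3e-12 to 0.128 over the alternatives). TLG2 (1.14), OM14 (1.26), ANT1 (1.24), SDH4 (1.15) and OST2 (0.81) were also higher with Sec63. SSH1 (-3.06 ± 0.21, edgeR adjusted p 0.013) and HEH2 (-1.92 ± 0.19, edgeR adjusted p 0.0145) were higher with the fusion that carried them. PDI1 differed by -1.54 and PRC1, vacuolar carboxypeptidase Y, by -1.59, while PMA1, the plasma membrane proton pump, did not pass (-1.29). It passed when replicate 1 or replicate 2 of Heh2-Ssh1 was left out (edgeR adjusted p 0.0105 and 6.9e-04) and with total footprints (edgeR adjusted p 0.0473, at -0.41). Without replicate 2 of Sec63 none of these genes passed (SSH1 at an edgeR adjusted p of 0.0618), and without replicate 1 of Sec63 PDI1, PRC1 and KAR2 did not (edgeR adjusted p 0.315, 0.0513 and 0.2).

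In single experiments, each gene's log2 pulldown over input was centred on cytosolic and nuclear genes. There is no replicate check of any value in the paragraphs on single experiments, and a bracket gives the 95% counting interval. Cytosolic BirA left the 14 secretory lists together slightly low (median -0.16, and -0.08 when centred on all genes), with ER chaperones at -0.08 (percentile 49.8 among 10000 random lists of like input level) and plasma membrane transporters at -0.26 (percentile 0). The highest genes were HSP12 at 0.47 [0.37, 0.57] and SSA4, a stress-induced Hsp70, at 0.44 [0.28, 0.60], and among the lowest was BPL1, the yeast cell's own biotin ligase, at -1.05 [-1.15, -0.95]. Ssh1-anchored BirA enriched the secretory lists by 1.95 after 2 min, with ER chaperones at 2.07 (percentile 100). SSH1 was again the highest gene, at 4.82 [4.73, 4.90], and DUR3, a urea transporter, the next that is free of overlaps, at 2.64 [2.35, 2.94].

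Ubc6-anchored BirA, which sits in the ER membrane apart from the translocon, enriched the secretory lists by 3.42 after 2 min and 2.74 after 7 min. ER chaperones reached 4.11 and 3.78, GPI-anchored proteins 3.98 and 3.65, and secreted proteins 4.03 and 3.57 (percentile 100 in each). Plasma membrane transporters stood lower, at 2.61 and 1.83, and tail-anchored proteins at 0.10 and 0.07. After 2 min MSB2 was at 4.72 [4.68, 4.77], EGT2, a GPI-anchored cell wall protein, at 4.62 [4.59, 4.66] and EUG1, an ER disulfide isomerase, at 4.55 [4.48, 4.62], and TPM1, tropomyosin, was among the lowest at -0.67 [-0.73, -0.60]. After 7 min MSB2 was at 4.68 [4.65, 4.70] and PDI1 at 4.40 [4.39, 4.41].

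**Figure D2:**
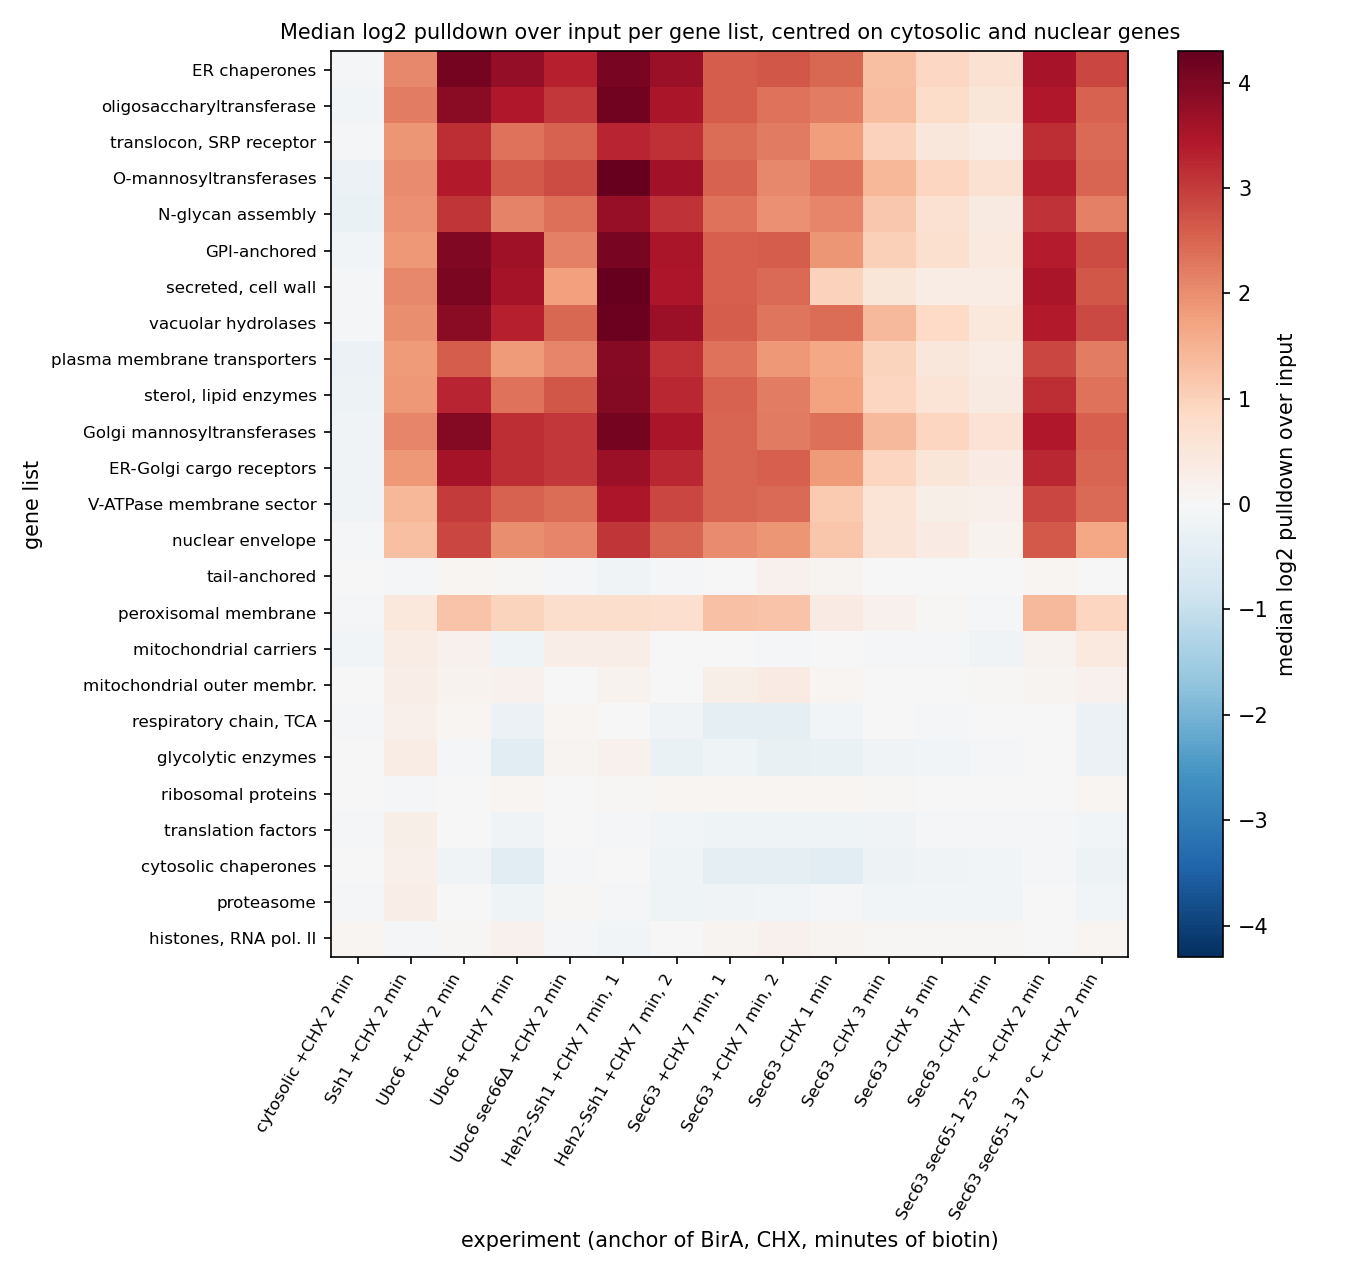
Median log2 pulldown over input (colour) of 25 gene lists in each of the 15 yeast experiments, centred on cytosolic and nuclear genes. The 14 secretory lists are positive in every ER experiment and between -0.30 and -0.04 with cytosolic BirA, while tail-anchored proteins stay between -0.14 and 0.17. With total footprints tail-anchored proteins can lie far lower, for example at -1.09 with Ubc6 after 2 min, which is not the lowest value.

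The sec66Δ comparison asked what changes at the Ubc6-anchored ligase when Sec66, a subunit of the Sec63 complex, through which proteins that do not need the signal recognition particle (SRP) enter the ER, is missing. The SEC66 gene itself (chromosome II, 578364 to 578984) had 1 input and 16 pulldown footprints in the sec66Δ libraries against 1429 and 6117 in the wild type. The secretory lists together were lower in sec66Δ by -0.70, beside -0.16 and -0.62 between the replicate experiments of Sec63 and of Heh2-Ssh1, so the shift of all lists was close to the larger of these replicate differences. With total footprints the sec66Δ shift was -0.37. The inputs differed as well, with ribosomal protein genes at 13.0% of footprints in the sec66Δ input and 17.9% in the wild-type input. The lists differed among themselves: GPI-anchored proteins were lower by -1.19, secreted and cell wall proteins by -1.18, and vacuolar hydrolases and ER chaperones by -0.80 and -0.75, while plasma membrane transporters were lower by -0.53, V-ATPase subunits by -0.47, peroxisomal proteins by -0.40 and tail-anchored proteins by -0.11 (0.22 with total footprints). The genes lowest in sec66Δ were TIR1 (-3.58 [-3.88, -3.28]; chromosome V, 175248 to 176012), TIR3 (-3.01 [-3.38, -2.64]), YLR194C (-3.00), PLB2 (-2.99), ECM33 (-2.93 [-2.95, -2.90]), RNY1 (-2.92), SIM1 (-2.90) and PEP4 (-2.88). They encode GPI-anchored or secreted surface proteins (TIR1, TIR3, YLR194C, PLB2, ECM33, SIM1), a secreted and vacuolar ribonuclease (RNY1) and vacuolar proteinase A (PEP4). PRC1 (-2.03) and PDI1 (-1.84) were also far lower, GAS1 (-0.88) and KAR2 (-0.70) were near the secretory median. SPP41, outside the secretome, was among the highest at 1.09 [0.89, 1.29]. The authors' class of 27 genes lower in sec66Δ had a median of -1.84 and their 10 higher genes 0.68, which are not independent evidence because the study chose them on these libraries. Genes predicted by the authors to use SRP had a median of -0.71 and those predicted not to use it -0.83.

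The sec65-1 comparison set a temperature-sensitive allele of the SRP subunit Sec65 at 37 °C for 30 min against 25 °C, with Sec63-anchored BirA for 2 min, so that heat and loss of SRP changed together. The heat shock was visible in the inputs: HSP26 took a 205-fold higher share of footprints at 37 °C, HSP12 85.4-fold, SSA4 74.9-fold, HSP30 19.7-fold, BTN2 11.6-fold, HSP104 11.5-fold, HSP78 10.6-fold and HSP42 9.89-fold. The unfolded protein response genes were less changed (ERO1 2.76-fold, KAR2 2.26-fold, SIL1 2.05-fold, PDI1 1.31-fold, LHS1 1.05-fold) and EUG1 was at 0.866-fold. The 138 ribosomal proteins had a median of -1.59 (percentile 0), beside 3.36 (percentile 100) for the heat shock and unfolded protein response list. Enrichment of the secretory lists went from 3.20 at 25 °C to 2.48 at 37 °C, a median difference of -0.71 (-0.41 with total footprints). Single lists lay between -0.54 (GPI-anchored proteins) and -0.89 (nuclear envelope proteins), with tail-anchored proteins at -0.08 and peroxisomal proteins at -0.05 (0.21 and 0.24 with total footprints). Genes predicted to use SRP had a median difference of -0.77 (355 genes) and genes predicted not to use it -0.71 (239 genes). The lowest gene was FIG2, a mating adhesin with few input footprints. Next came SSA3 (-2.46), HSP26 (-1.92 [-2.01, -1.84]), ARV1 (-1.87 [-2.15, -1.59]), a protein of ER sterol distribution, YDR476C (-1.69), PUT1 (-1.68), LDB16 (-1.66) and GET2 (-1.63), a receptor subunit for tail-anchored proteins. The highest were SAR1 (1.45 [1.38, 1.51]), the GTPase of COPII vesicles, CCC1 (1.16), a vacuolar iron transporter, and VPS20 (1.14). KAR2 and PDI1 were at -0.57 and -0.52.

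**Figure D3:**
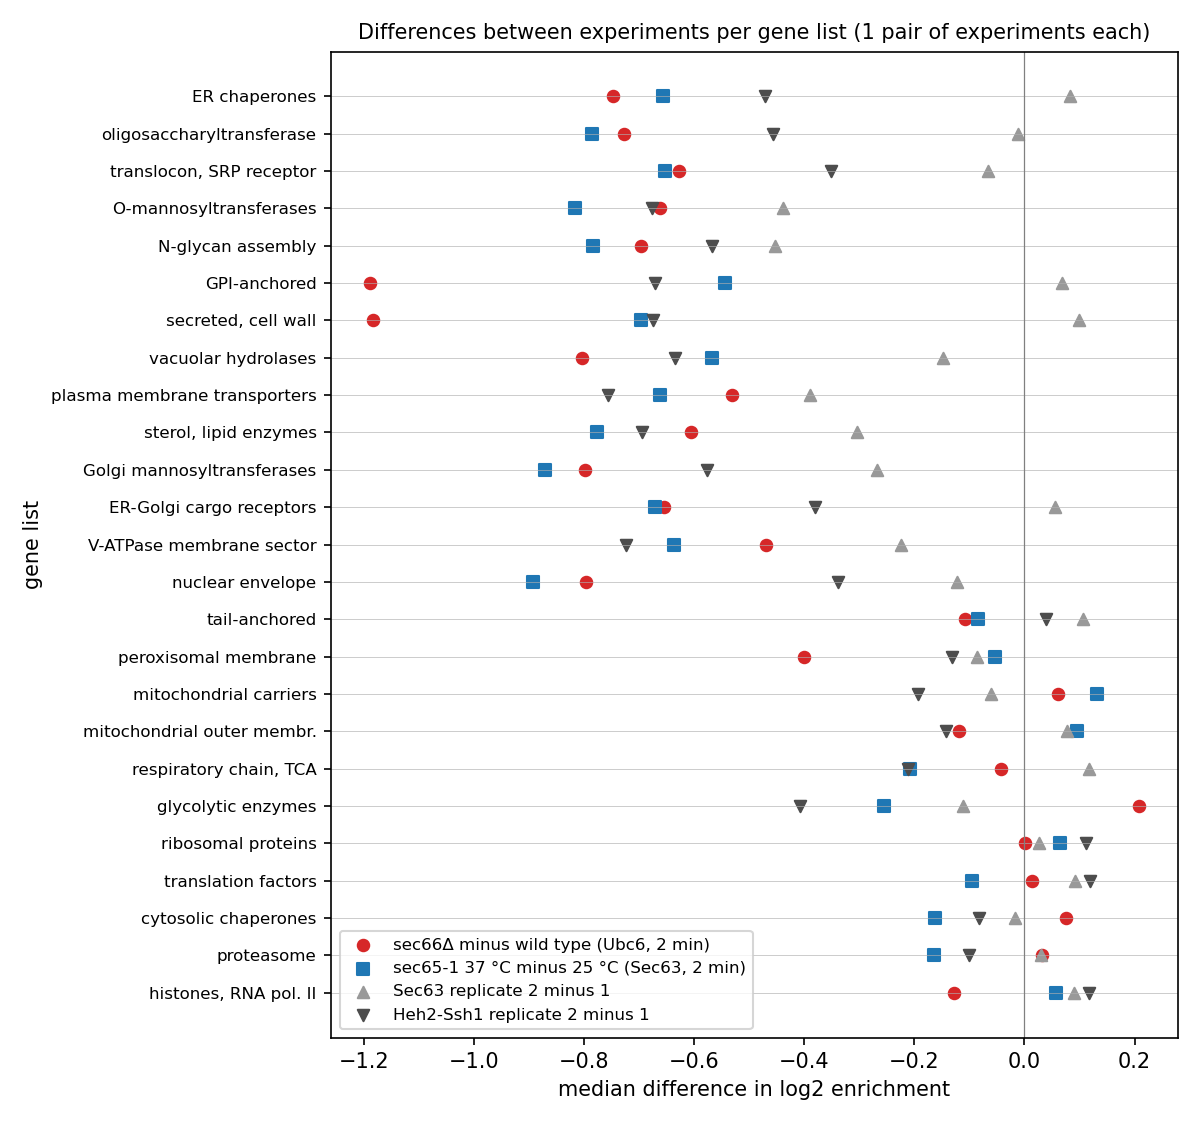
Median difference in log2 enrichment of each gene list between sec66Δ and wild type and between sec65-1 at 37 °C and at 25 °C, beside the difference between the replicate experiments of Sec63 and of Heh2-Ssh1 (points, 1 pair of experiments each). In sec66Δ the GPI-anchored and secreted lists lie lowest, at -1.19 and -1.18, and in sec65-1 the secretory lists lie between -0.89 and -0.54.

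Without cycloheximide, Sec63-anchored BirA was given biotin for 1, 3, 5 or 7 min. The secretory lists were enriched by 1.84, 1.00, 0.59 and 0.39 at these times, against 2.47 and 2.22 in the experiments with cycloheximide. The share of secretome footprints in the pulldown was 39.3%, 27.1%, 21.9% and 19.6%. KAR2 went from 2.82 to 1.63, 1.10 and 0.81, DAP2, a vacuolar membrane protease, from 2.74 to 1.89, 1.22 and 0.84, PMA1 from 1.64 to 0.94, 0.53 and 0.38, and PDI1 from 1.66 to 0.75, 0.49 and 0.34. The highest genes at 1 min included MSB2 (1306 residues) at 3.44 [3.40, 3.48], HKR1 (1802) at 3.34, PEP1 (1579) at 3.33, IRE1 (1115), the unfolded protein sensor, at 3.32 and LHS1 (881) at 3.31. Among the lowest were long proteins outside the secretome, FAS1 (2051) at -1.10 [-1.12, -1.09], MLP1 (1875) at -1.04 and URA2 (2214) at -1.03. At 7 min MSB2 (1.53) and PEP1 (1.39) still led among annotated genes, and MDN1 (-1.30) and DYN1 (-1.13) were among the lowest.

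Enrichment after 1 min without cycloheximide was set against the mean after 7 min with it, so drug and labelling time changed together. At 1 min without the drug, O-mannosyltransferases (0.09), Golgi mannosyltransferases (0.03), vacuolar hydrolases (-0.02) and N-glycan assembly genes (-0.07) stood close to their mean with cycloheximide, and ER chaperones were at -0.16. V-ATPase membrane subunits (-1.17), secreted and cell wall proteins (-1.14), peroxisomal membrane proteins (-0.83), nuclear envelope proteins (-0.71), cargo receptors (-0.68), sterol and lipid enzymes (-0.59), GPI-anchored proteins (-0.57), translocon genes (-0.50), plasma membrane transporters (-0.47) and the oligosaccharyltransferase (-0.34) were lower relative to cytosolic and nuclear genes. With total footprints ER chaperones stood at 0.18, vacuolar hydrolases at 0.33, N-glycan assembly genes at 0.28 and the oligosaccharyltransferase at 0.011. The authors' class of 190 genes whose enrichment depends on cycloheximide had a median of 0.08 at 1 min against 1.85 for their independent class, a class that was trained on the same libraries and is not independent evidence.

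**Figure D4:**
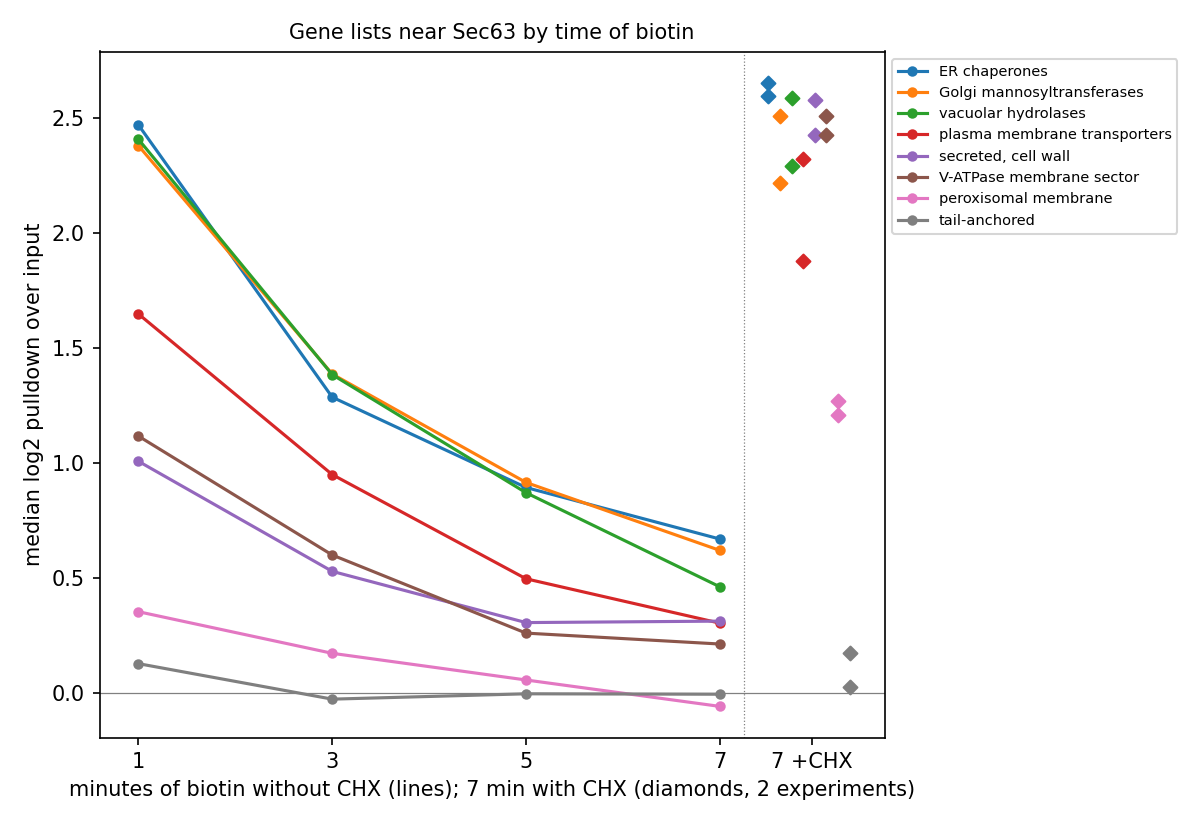
Median log2 enrichment of 8 gene lists against minutes of biotin without cycloheximide (lines, 1 experiment per time), with the 2 experiments at 7 min with cycloheximide as separate points. The ER chaperones go from 2.47 at 1 min to 0.67 at 7 min, and tail-anchored proteins stay between -0.03 and 0.13.

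In HEK293T cells BirA was fused to Sec61β, a subunit of the human translocon, and given biotin for 10 min with cycloheximide (1 experiment). Secretome genes took 12.2% of input footprints and 36.2% of the pulldown, with Wilson 95% intervals within 0.0644 percentage points. Of 4804 genes with at least 100 input footprints, 874 were in the authors' secretome, and their median was 2.26 relative to genes in none of the secretome, mitochondrial and peroxisomal classes (bootstrap 95% interval over genes 2.14 to 2.32, 4.80-fold). The 363 genes with a predicted signal peptide had a median of 2.75 and the 392 with a transmembrane segment and no signal peptide 2.11 (percentile 100 in each). Mitochondrial genes outside the secretome stood at 0.41 (581 genes). Genes outside the secretome in the deposited peroxisomal class, a broad class of 1445 genes, stood at 0.37 (712 measured). The percentile was 100 for these mitochondrial and peroxisomal genes too, so it does not set the secretory classes apart. Among the 100 highest genes 92 were in the secretome, and among the 100 lowest 4 were. Of 803 genes above 1, 640 were in the secretome. The table pairs its genes with transcript and protein identifiers and not with symbols, so no human gene is named: the highest were uc001vqx.3 at 3.95 [3.76, 4.14] and uc002zhi.3 at 3.87, and the lowest were uc011mfh.2 at -2.14 and uc002kxc.4 at -2.13.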

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

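The tests of the SSH1 pattern in this part were chosen only after the result was seen, while the test of the difference between the fusions was planned.

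The 2 fusions differed in the direct test (Sec63 minus Heh2-Ssh1, edgeR quasi-likelihood, 2 experiments each), with 169 genes higher with Sec63 and 667 higher with Heh2-Ssh1. A shift common to secretory genes was not separated from differences of single genes. Without replicate 2 of Sec63 the edgeR counts were 0 and 1 (195 and 607 at an unadjusted p under 0.05, with DESeq2 on all libraries at 103 and 586). In that edgeR fit the difference was -2.88 for SSH1 and 1.90 for ERG9. Without replicate 1 of Sec63 the counts were 84 and 523, without replicate 1 of Heh2-Ssh1 339 and 739, and without replicate 2 of Heh2-Ssh1 774 and 1082. With total footprints the balance turned, to 3816 and 260. The genes with the largest differences towards Sec63 were YBR182C-A (3.10), ERG9 (1.78), CAF40 (1.76), YDR476C (1.58), MOB2 (1.54), COX20 (1.49), AGA2 (1.48) and PET100 (1.47). COX20 and PET100 assist the assembly of cytochrome oxidase in the inner mitochondrial membrane, ERG9 makes squalene at the ER, AGA2 is part of the mating agglutinin, MOB2 belongs to a kinase complex and CAF40 to the CCR4-NOT deadenylase. The largest towards Heh2-Ssh1 were COX2 (-4.19), YJL047C-A (-4.18), YOR390W (-3.66), HXT7 (-3.49), SSH1 (-3.06), COX1 (-2.72), BI4 (-2.68) and COS7 (-2.64).

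Several of these genes have few or shared footprints. COX1, COX2 and BI4 lie on the mitochondrial genome, and COX2 had 13, 270, 58 and 147 input footprints and 0, 7, 34 and 34 in the pulldowns. HXT7, COS7 and YOR390W have near-identical copies, and YOR390W had 33, 14, 16 and 5 input footprints. Without replicate 1 of Heh2-Ssh1 the HXT7 call ended (edgeR adjusted p 0.0791, and 1.5e-28 to 0.835 over the alternatives), and without its replicate 2 that of YBR182C-A did (edgeR adjusted p 0.077). Without replicate 1 of Sec63 the calls of YBR182C-A and BI4 ended (edgeR adjusted p 0.188 and 0.117). YBR182C-A passed in 7 of 11 alternatives and BI4 in 5 of 11. Without replicate 2 of Sec63 the calls of all these genes ended but that of HXT7.

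In the 3 experiments with an Ssh1 fusion, SSH1 lay at least 1.34 above the secretory median, and in the other ER experiments at most 0.16 above it. The tables argue against noise from few footprints, since the smallest excess was 4.55 times the standard deviation between the Heh2-Ssh1 experiments of 220 secretome genes of like input (0.294). They also argue against a higher gain for ER genes in general, since the excess in every Ssh1 experiment was above that in each other ER experiment, by 1.18 or more. What stays open is the hypothesis that ribosomes may be biotinylated by the BirA they have just made at the N-terminal end of the nascent fusion. UBC6, also an N-terminal fusion, was higher in its own 3 experiments (0.24 to 0.61) than in each of 12 others (at most 0.05). Most UBC6 footprints there can come from the intact gene. An exact one-sided permutation over experiments gave p 0.0022. That p is descriptive only, because the 3 experiments share 1 fusion and 8 of the others share Sec63-anchored BirA. SEC63, with BirA at its C-terminal end, lay at percentiles 85.5 to 93.3 in its 8 experiments, without a ranking in other fusions.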

How the results depend on the processing

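The fit without the 37 °C libraries and centring without ribosomal proteins were tests chosen only after the results were seen, and the other alternatives were planned. The cause of the changes below was not tested, except where the alternative tests fewer genes or samples.

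The enriched counts near Sec63 (1043 to 1716 against 1306) and near Heh2-Ssh1 (828 to 1148 against 1052) stayed within 1.5 times in the alternatives tried. The depleted counts did not. Near Sec63 (1307) they were 679 with DESeq2, 3354 with total footprints, 839 when scaled on the reference genes and 124 at a log2 fold change of 1 or more. Near Heh2-Ssh1 (764) they were 231, 4612, 419 and 9, and 494 with at least 100 input footprints, 347 with the compared fusions alone and 1628 without the 37 °C libraries. In the difference of the fusions, 103 genes were higher with Sec63 with DESeq2, 3816 with total footprints and 62 at a log2 fold change of 1 or more, against 169. In the same test 260 were lower with total footprints, 414 with the compared fusions alone and 281 without the 37 °C libraries, against 667.

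Without the replicate block, the term that pairs each pulldown with its input, the depleted counts were 481 and 166, and in the difference 0 genes passed either way in edgeR (213 and 646 at an unadjusted p under 0.05, and with the block 103 and 586 in DESeq2). With 1 replicate left out, the depleted counts ranged from 232 to 1674 near Sec63 and from 232 to 1447 near Heh2-Ssh1, and the difference from 0 to 774 genes higher and from 1 to 1082 lower.

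Medians of lists changed sign in some settings. With total footprints, mitochondrial outer membrane genes near Sec63 were at -0.32 and peroxisomal genes near Heh2-Ssh1 at -0.68, and in the difference the translocon (0.10), V-ATPase (0.14), nuclear envelope (0.20), mitochondrial carriers (0.58), respiratory genes (0.65), translation factors (0.63) and cytosolic chaperones (0.53) turned positive. Scaled on the reference genes, tail-anchored (0.031) and ribosomal protein genes (0.044) near Sec63, and mitochondrial outer membrane (2.5e-04) and ribosomal protein genes (0.038) near Heh2-Ssh1 turned positive. With at least 100 input footprints the ribosomal proteins were at 2.0e-04 near Sec63 and 0.014 near Heh2-Ssh1, and with the compared fusions alone at 0.010 near Heh2-Ssh1. With 1 replicate left out, tail-anchored genes near Sec63 ranged from -0.091 to 0.010, the latter without replicate 1 of Sec63. In single experiments, tail-anchored genes were at -1.09 with total footprints and -0.097 when centred on all genes (Ubc6, 2 min), and at -0.15 with total footprints without cycloheximide at 1 min. Peroxisomal genes in sec65-1 were at 0.24 with total footprints and 0.069 without ribosomal proteins.

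With an estimated correlation camera called 0 lists in each comparison (0 at an unadjusted p under 0.05), against 20, 19 and 16. That version rested on 2 residual degrees of freedom, so correlation between genes was not shown to be what removed the calls. In single experiments, centring on total footprints gave secretory medians of 1.35 (Ssh1), 2.24 and 1.70 (Ubc6 at 2 and 7 min), 1.72 (Sec63 with cycloheximide) and 1.54 (HEK293T), and centring on all genes 2.10 for HEK293T, all in the same direction. Of 12 such medians 7 moved by less than the replicate spread in every alternative, as did 32 of 65 named genes in single experiments and 20 of 46 list medians. Of 79 tested gene values, 33 kept their direction and side of the threshold in every alternative, and none changed sign past the threshold. None of 75 tested list results was the same in every alternative, and 4 of 12 counts were. Input minimums and the depth of the libraries limited values of genes with few footprints.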

Other observations

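The tests of SRP-dependent genes and of sec66Δ were chosen only after the result was seen, while those of the length trend were written before.

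Outside the secretome, pulldown over input went with protein length. The rank correlation across genes, which are not independent replicates, ran from -0.79 without cycloheximide at 1 min to 0.40 with Ssh1, was -0.36 with cytosolic BirA, and had a median size of 0.478 over the 15 experiments. The tables argue against input abundance, since within bins of abundance the median size was 0.4677, and against short ribosomal and other reference genes alone, since without them it was 0.4675. Differences between input libraries cannot be told apart from the trend, because with 1 common input it was 0.266, a ratio to its own-input size of 0.556 (bootstrap 95% interval over experiments 0.467 to 0.926). With the common input the correlation kept its sign in 14 of the 15 experiments, but experiments differed in its size. It was -0.68 against -0.79 without cycloheximide at 1 min and 0.37 against 0.40 with Ssh1. Without cycloheximide at 7 min it was -0.22 against -0.61. No biological explanation of the trend was tested.

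The secretory lists were lower in sec65-1 at 37 °C and in sec66Δ. For sec65-1, a lower gain of the whole experiment and a greater loss of SRP-dependent genes cannot be told apart. At matched enrichment at 25 °C the drop of SRP-dependent genes differed from that of independent genes by -0.10 (bootstrap 95% interval over genes -0.20 to -0.0020, 355 and 239 genes), and the same value between replicates was -0.18 and -0.02, while heat and the allele changed together. For sec66Δ, secreted and GPI-anchored genes dropped more than other secretome genes of like enrichment by -0.52 (-1.04 to -0.08, 33 genes). The same value was 0.17 and -0.03 between replicates of Sec63 and of Heh2-Ssh1. The interval lies below both replicate values, but it takes in a difference of the same size as the 0.17. With 1 experiment per genotype, a lower gain can therefore not be told apart from a loss of certain proteins for this class. Nor can it for the genes far below the rest, since 17 of 861 secretome genes (1.97%, Wilson 95% interval 1.24% to 3.14%) lay more than 1 below genes of like wild-type enrichment, against 0 of 890 and 6 of 900 (0.667%, at most 1.45%) between replicates of Sec63 and of Heh2-Ssh1, with 1 experiment per genotype.

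By the deposited RPKM values, scaled by the authors, SSH1 had 27.9 and 21.2 RPKM in the Heh2-Ssh1 inputs and 68.1 in the Ssh1 input, against 111 in sec65-1 at 37 °C and 254 to 310 in the other inputs. HEH2 had 31.0 and 34.9 RPKM in the Heh2-Ssh1 inputs against 17.2 to 24.8 elsewhere. SEC65 had 49.3 RPKM at 37 °C and 82.7 at 25 °C.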
